A study of Mus musculus with 7 samples.

How the data were processed

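RNA from sorted marrow cells of 4 PBS-treated and 3 DT-treated mouse samples was analysed. Per the labels' protocols, libraries were made from 1 ng of total RNA with a SMARTer ultra-low input kit and 14 cycles of amplification, and sequenced as single reads of 50 bases on an Illumina HiSeq instrument. Such amplification copies molecules, so intervals and floors based on reads cover counting error only. STAR 2.5.3a, Partek and the mm10 build are named per the submitters' processing notes; the annotation, the quantification settings and strand use are not given in the sources used here.

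The authors deposited 1 table of 50435 gene rows whose name states FPKM, but its values behave as RPM. After subtraction of an offset of 0.0001, the most frequent value of a library was shared by 1029 to 1206 genes and taken as its step. Values divided by gene length would not be shared in this way. The step was not compared between genes of different lengths. The design had assumed FPKM, and the same limma test on log2(value + 1) was kept. Per library, 60.5% to 62.6% of values up to 20 steps were whole within 0.02 of a step, so whole reads were not recovered and no count model was the main test. The step implied 33200000 to 51200000 reads per library. Column sums were 75.4% to 82.2% of the total the unit implies. The 10 most abundant genes held 6.25% to 11.2% of the values. All 13 mitochondrially encoded genes sat at the offset in every library, so no mitochondrial share was computed. Gm28437, Gm10925 and Gm28661, predicted genes, were lower in DT without overlap, at 6530 ± 631, 6234 ± 479 and 3171 ± 356 RPM in PBS (SD, n = 4) and 3731 ± 575, 3527 ± 441 and 1779 ± 211 RPM in DT (SD, n = 3). Whether they hold reads of mitochondrial transcripts, and so bear on RNA quality, was not tested. A total of 26 rows carry names turned into dates by a spreadsheet; they stayed in the counts and are not named.

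Genes with a mean of at least 1 RPM over all 7 libraries were tested (14100). Values were transformed as log2(RPM + 1), so changes of low genes are understated. Limma 3.58.1 in R 4.3.3 was fitted with an intensity trend, DT against PBS, two-sided, with Benjamini-Hochberg adjustment at 0.05. Folds given as such are ratios of group means in RPM. Gene lists (30 for pathways, 10 for cell types, 3 for RNA quality or sex) were fixed before the data were examined, and lists with at least 5 tested genes entered camera with a preset correlation of 0.01. Adjusted p was taken over the pathway lists and, separately, over the other lists. Camera with an estimated correlation and fry, which tests whether genes of a set move on balance one way, were run as alternatives. Sort and target genes were compared by exact two-sided permutation of the absolute difference of means over 35 splits; 1 of these genes is not reported here. Samples sharing a replicate number were checked for pairing.

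Genes named in the text follow a rule fixed before the data were examined. It takes the 12 largest rises and 12 largest falls among genes past the threshold whose groups do not overlap, leaving out predicted genes, RIKEN clones, pseudogenes, microRNAs, snoRNAs and immunoglobulin or T cell receptor segments. It adds the sort and target genes, up to 4 members per list past the threshold with the smallest p (or the 2 with the smallest p where none passes), and the 2 most abundant members of each cell type list. Cdh5, Egfl7, Erg, Vwf, Plvap, Lyve1, Cd79a, Ltf, Klf1, Hbb-bs, Xist, Gm28437, Gm10925, Gm28661, the Y-linked genes and the 12 endothelial genes that were summed were chosen after their values were seen.

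The method was tested on simulated DT against PBS data with 200 changed genes. Among 14041 genes, limma recovered 27.6% of 98 genes changed 2-fold and 76.6% of 94 changed 4-fold that passed the filter, and 10% of calls were false. Camera found the raised list and called 0 of 15 unchanged lists. This cannot vouch for the list calls in the data, where genes of some lists move together strongly. The estimated correlation there ran from -0.0956 for coagulation to 0.912 for erythroid genes, and with such estimates 0 lists passed. The simulation also changed far fewer genes than the 4516 past the threshold in the data. Alternatives covered the pseudocount, the filter, 3 other scalings, the variance trend, sample weights, a replicate block, a fold minimum and leaving out each library. Added after seeing the data were limma voom on reads estimated from the steps and leaving out both replicates numbered 1. Gene positions are from GENCODE vM21 on mm10. Transcript lengths were found for 97.3% of tested genes, and the Spearman rho of log2 change with length across genes, which are not independent replicates, was -0.022.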

Results

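RNA was sequenced from mouse bone marrow cells sorted as sinusoidal endothelial cells, the lining of the thin-walled venous vessels through which blood cells leave the marrow. The recipients had been irradiated and given marrow in which the diphtheria toxin receptor is placed under Zbtb46, a transcription factor gene used to mark classical dendritic cells. At 8 weeks the mice received 200 ng of diphtheria toxin (DT), which kills cells carrying the receptor, or PBS alone, and marrow was taken 1 day later. The labels describe 4 PBS and 3 DT samples as biological replicates. The sort kept CD31-positive, Sca1-negative cells and excluded cells stained for CD45, Ter119, Gr1 or CD11b. Values are in RPM (reads per 1e6 reads of a library). The most frequent low value of a library, taken as 1 read, put its reads between 33200000 and 51200000. A signal of 3 reads equals 0.0585 to 0.0904 RPM, which covers counting error only. Pearson correlations of log2 values between libraries were 0.908 to 0.963 within PBS, 0.962 to 0.966 within DT and 0.798 to 0.875 between groups.

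Many genes specific to endothelial cells were at a few RPM or less, whereas genes of blood cells were abundant. Cdh5, the endothelial cadherin, was at 0.811 ± 1.27 RPM in PBS (SD, n = 4) and 2.10 ± 1.18 RPM in DT (SD, n = 3). The sum of 12 endothelial genes (Cdh5, Kdr, Tek, Tie1, Flt1, Esam, Robo4, Cldn5, Stab1, Stab2, Flt4 and Emcn), a set chosen after their values were seen, lay between 1.45 and 9.35 RPM in PBS and between 10.2 and 18.7 RPM in DT. The fixed list of 20 pan-endothelial genes, which takes in genes also expressed by leukocytes, summed to 743 ± 133 RPM in PBS and 697 ± 13.2 RPM in DT. The fixed sinusoidal list summed to 88.7 ± 10.2 and 318 ± 147 RPM. Its member Vcam1, also known from macrophages, was at 10.6 ± 2.74 RPM in PBS and 192 ± 126 RPM in DT. Its members Stab1, Stab2, Flt4, Emcn, Plvap and Lyve1 averaged at most 1.76 RPM in either group. Egfl7 and Erg, endothelial genes chosen in the same way, were higher, at 27.9 ± 14.4 and 19.9 ± 10.2 RPM in PBS and 13.9 ± 3.33 and 12.1 ± 3.62 RPM in DT. Eng, also found on blood cell precursors, fell from 21.8 ± 10.9 to 4.12 ± 2.15 RPM. Pecam1, which encodes the sorted antigen CD31 and is also expressed by leukocytes, was at 82.3 ± 21.5 RPM in PBS and 80.3 ± 7.91 RPM in DT. Its log2 difference did not hold a direction under quantile or median-ratio scaling. Cd79a, part of the B cell receptor, was at 1268 ± 258 RPM in PBS and 718 ± 36.2 RPM in DT. Ptprc, which encodes the excluded antigen CD45, was at 171 ± 53.4 RPM in PBS and 473 ± 64.0 RPM in DT. The comparisons describe the RNA of the sorted samples as a whole, without assigning it to endothelial cells.

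**Figure D1:**
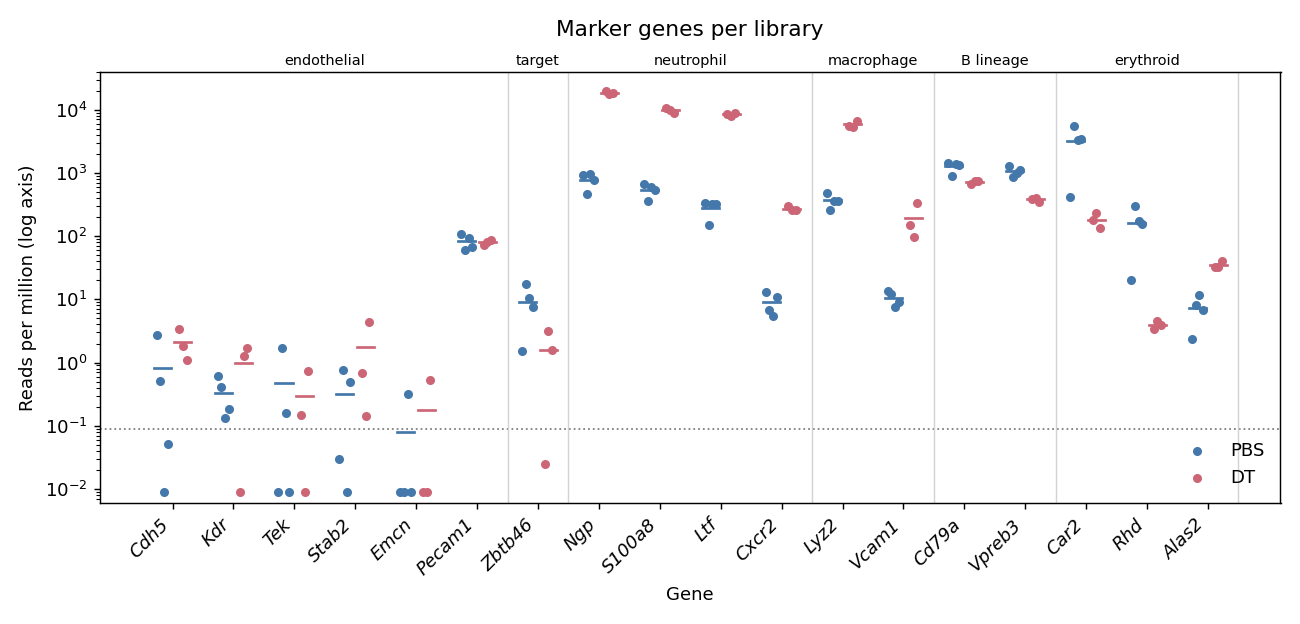
RPM on a log axis for marker genes in the 4 PBS (blue) and 3 DT (red) libraries; points are libraries, bars are group means, the dotted line is the highest 3-read floor of any library, and genes listed at the lowest value of the table are drawn at the bottom. Cdh5 averaged 0.811 RPM in PBS and 2.10 RPM in DT, whereas Ngp averaged 777 and 18499 RPM.

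The comparison of DT with PBS asked how the sorted cells' RNA differs 1 day after DT, given to ablate Zbtb46-expressing cells. The largest rises included Cxcl2, Il1b, Il1r2 and Cd177, and the largest falls included the erythroid genes Rhd, Car1, Car2, Rhag and Ermap. Of 14100 genes tested with limma, 1894 were higher and 2622 lower in DT at an adjusted p under 0.05. Changes of at least 2 in log2(RPM + 1) were mostly rises, with 720 genes higher and 116 lower. At 4 or more on that scale, 111 genes were higher and 8 lower. That scale understates changes of low genes, so these are not counts by ratio of group means. The median log2 change of all tested genes was -0.23, so small falls should be read against that shift. Median-ratio scaling moved the median to -0.01 and gave 2394 genes higher and 1255 lower, so that 65.6% of calls were rises against 41.9% as deposited. The number of genes lower was 1500 without DT replicate 1, 1609 without DT replicate 2 and 1208 without DT replicate 3. The groups did not overlap in 40.9% of tested genes, where chance gives 5.71%. The first principal component held 64.4% of the variance and separated the groups.

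Among the 12 largest rises were chemokine, cytokine and surface receptor genes. Jchain, the joining chain of secreted antibodies, rose by 5.80 on the log2 scale, from 11.2 ± 18.4 to 308 ± 65.4 RPM (limma, adjusted p = 0.000981). Cxcl2, a chemokine that attracts neutrophils, rose from 0.809 ± 0.593 to 92.3 ± 69.2 RPM. Il1b, which encodes the cytokine interleukin-1 beta, rose from 1.80 ± 1.19 to 88.5 ± 23.8 RPM. Il1r2, the decoy receptor of that cytokine, rose 46.8-fold and Il1f9, a related cytokine, 48.4-fold. Cd177, a neutrophil surface protein, rose from 42.7 ± 17.9 to 1482 ± 118 RPM. The rest of the 12 were Pram1, Lilrb4a, Mmp25, Lrg1, Cd300lf and Lilr4b, which rose by 5.05 to 5.47 on the log2 scale. 

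All 17 neutrophil genes rose, over all genes and adjusted over the list alone, with a median log2 change of 4.22 (camera, preset correlation, adjusted p = 7.75e-24; adjusted p = 0.115 with an estimated correlation). Ngp, a granule protein of neutrophil precursors, went from 777 ± 222 to 18499 ± 978 RPM. S100a8, a cytosolic protein of neutrophils, went from 537 ± 126 to 9818 ± 773 RPM, and Ltf, the granule protein lactoferrin, from 282 ± 87.2 to 8419 ± 500 RPM. Mmp9, a matrix-degrading enzyme, rose from 21.6 ± 2.00 to 650 ± 37.3 RPM, and Mmp8 and Camp rose 21.6-fold and 21.1-fold. Cxcr2, the receptor for Cxcl2 on neutrophils, lies on chromosome 1 at 74153989 to 74161246 in mm10 (GENCODE vM21) and rose 30.3-fold, from 9.004 ± 3.48 to 272 ± 21.6 RPM (limma, adjusted p = 2.48e-06). On its list of 5 tested genes of the Cxcr2 axis, Cxcr2 and Cxcl2 rose and 3 genes did not pass. That list had a median log2 change of -0.16 and missed the threshold (camera, adjusted p = 0.0647), but passed it without a filter (0.0156) and without PBS replicate 2 (0.0433), DT replicate 1 (0.0381) or DT replicate 3 (0.0432).

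Monocyte, macrophage, T cell and natural killer cell genes rose as well. Of 17 monocyte and macrophage genes 15 rose, 16 when adjusted over the list alone, with a median log2 change of 3.22 (camera, adjusted p = 4.46e-14; adjusted p = 0.120 with an estimated correlation). Lyz2, the myeloid lysozyme, rose from 366 ± 95.3 to 5890 ± 722 RPM, Ly6c2 7.65-fold and Csf1r, the receptor for the macrophage growth factor, 6.90-fold. Of 14 T and natural killer cell genes 12 rose, 13 when adjusted over the list alone and 3 with a minimum mean of 5 RPM, where fewer are tested (camera, adjusted p = 2.91e-09; adjusted p = 0.115 with an estimated correlation). Nkg7, found in cytotoxic granules, rose from 28.0 ± 14.5 to 270 ± 20.8 RPM and Cd3e, part of the T cell receptor complex, from 0.802 ± 0.474 to 10.4 ± 2.13 RPM. Cd2 was at 56.3 ± 19.2 and 56.5 ± 7.25 RPM.

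Erythroid genes moved in both directions. Of 17 tested, 10 fell and 4 rose, or 11 and 5 when adjusted over the list alone. Without a filter 6 fell and 1 rose, and with voom on estimated reads, tried after seeing the data, 5 fell and 4 rose. Car2 and Car1, carbonic anhydrases of red cell precursors, fell from 3159 ± 2088 to 180 ± 48.2 RPM and from 2160 ± 1420 to 75.9 ± 29.0 RPM. Rhd, which encodes a blood group protein, fell from 162 ± 114 to 3.96 ± 0.589 RPM, and Klf1, a transcription factor of the lineage, from 63.6 ± 45.3 to 2.69 ± 2.22 RPM. Alas2, which makes heme in late precursors, rose from 7.30 ± 3.90 to 34.96 ± 4.10 RPM and the globin Hbb-bs from 320 ± 182 to 991 ± 148 RPM. The members moved both ways and the list did not pass (camera, adjusted p = 0.225). It passed under median-ratio scaling (0.0446) and without PBS replicate 1 (0.00271), the PBS library with the lowest value of all 10 genes that fell. The other large falls outside that list were Cldn13, Atp7b, Atp1b2, Prss50, Gfi1b, Aldh1a7 and Epdr1, with Gfi1b, a transcription factor of erythroid and megakaryocyte cells, falling from 136 ± 93.2 to 8.60 ± 2.26 RPM. Rhag and Ermap, both red cell membrane genes, fell by 4.14 and 4.25 on the log2 scale. With voom Ermap, Cldn13, Rhag, Atp7b, Prss50, Aldh1a7 and Epdr1 kept their direction but missed the threshold, with adjusted p from 0.0667 to 0.164.

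Of 16 B-lineage genes tested 9 fell, Jchain rose and 6 did not pass, and 9 fell while Jchain and Igkc rose when adjusted over the list alone (camera, adjusted p = 0.0296; adjusted p = 0.524 with an estimated correlation). Without PBS replicate 1 or PBS replicate 3 the adjusted p was 0.0678 and 0.0679, and it was 0.0539 without the trend. Vpreb3, a gene of B cell precursors, fell from 1062 ± 176 to 383 ± 29.0 RPM, Rag1, which cuts antigen receptor genes, from 152 ± 22.3 to 52.997 ± 12.9 RPM and Pax5, which commits cells to the lineage, from 259 ± 60.6 to 117 ± 19.2 RPM. Ighm was at 3076 ± 846 and 2607 ± 443 RPM and Igkc at 1076 ± 487 and 1877 ± 326 RPM, and Igkc passed without PBS replicate 1 (0.0141) or 3 (0.0398). Hematopoietic progenitor genes had 5 rises and 2 falls among 11 and missed the threshold (camera, adjusted p = 0.0910), with 3 rises without DT replicate 3 or with a minimum mean of 5 RPM. Myb, a transcription factor of progenitors, fell from 398 ± 59.5 to 136 ± 25.1 RPM. None of 12 megakaryocyte and platelet genes passed (camera, adjusted p = 0.916), and Pf4 was at 45.8 ± 25.5 and 41.1 ± 27.5 RPM.

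Zbtb46, the gene driving the receptor, was at 9.21 ± 6.62 RPM in PBS and 1.57 ± 1.55 RPM in DT. The difference missed the threshold (limma, adjusted p = 0.0556; exact permutation p = 0.114, n = 4 and 3). Without PBS replicate 1, where Zbtb46 was at 1.54 RPM, its adjusted p was 0.00451, and it was 0.0490 under quantile normalization and 0.0129 with sample weights. In PBS replicates 1 to 4 Zbtb46 was at 1.54, 17.5, 10.4 and 7.45 RPM, where the erythroid genes Klf1 and Rhd were at 5.15, 115, 73.1 and 61.2 RPM and at 20.48, 300, 172 and 157 RPM; Klf1 and Rhd fell in DT. Other genes of classical dendritic cells did not follow one direction, with 5 of 8 higher and 2 lower (camera, adjusted p = 0.0326; adjusted p = 0.514 with an estimated correlation). The count of rises was 2 without DT replicate 2, without a filter or with a minimum mean of 5 RPM, and 3 without DT replicate 3, and the list missed the threshold without PBS replicate 2 (0.0611) or PBS replicate 3 (0.0651), under median-ratio scaling (0.0525) and with a minimum mean of 5 RPM (0.288). Naaa, a lysosomal enzyme, rose from 6.55 ± 1.60 to 38.2 ± 3.89 RPM and Cd209a, a lectin, from 2.11 ± 0.874 to 12.6 ± 0.546 RPM. Of the genes for sorted antigens, Itgam, which encodes CD11b, rose 11.8-fold, Ly6g, part of the Gr1 epitope, 12.4-fold and Ly6a, which encodes Sca1, 6.90-fold. In exact permutation tests over 35 splits, the smallest p possible is 0.0286, reached by Ly6a, Ptprc, Itgam, Ly6g, Ly6c1, Cxcr2 and Vcam1, and 0.0571 after adjustment over the 14 genes. Hbegf, Kitl, Sele and Cxcl12 had exact p of 0.714, 0.629, 0.429 and 0.171.

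Among the 29 pathway lists tested, 12 were higher and 2 lower with camera at the preset correlation. None passed with an estimated correlation, where the lowest adjusted p was 0.126. The neutrophil list summed to 3488 ± 1118 RPM in PBS and 64270 ± 1625 RPM in DT. List comparisons of whole samples cannot tell a shift in the mix of cells from a change within cells. Of 11 chemokine genes 8 rose, in the list alone too (camera, adjusted p = 6.91e-06), including Ccl6 and Ccl5, which rose 12.5-fold and 13.8-fold. Type I interferon targets rose in 16 of 30 genes, 17 adjusted over the list alone and 9 without DT replicate 3 (camera, adjusted p = 2.25e-07). Oas3 and Oasl2, which sense or respond to double-stranded RNA, rose 11.2-fold and 10.4-fold. Antigen presentation and interferon gamma genes rose in 12 of 32 and fell in 1, with 14 rises adjusted over the list alone and 6 without DT replicate 3 (camera, adjusted p = 6.91e-06), with Cd74, the class II chaperone, going from 544 ± 192 to 1831 ± 353 RPM. Immediate early genes rose in 13 of 19 and fell in 1, with 14 rises adjusted over the list alone (camera, adjusted p = 2.25e-07), with Fos from 15.2 ± 6.30 to 244 ± 112 RPM, and NF-kB targets rose in 10 of 23 and fell in 1 (13 rises adjusted over the list alone and 6 with a minimum mean of 5 RPM; camera, adjusted p = 3.10e-05). With an estimated correlation these 5 lists had adjusted p of 0.126, 0.219, 0.262, 0.219 and 0.126.

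Of 24 hypoxia and glycolysis genes 12 rose and 1 fell, with 12 rises adjusted over the list alone (camera, adjusted p = 2.14e-05; adjusted p = 0.126 with an estimated correlation), with Pkm, the last enzyme of glycolysis, from 217 ± 60.5 to 1640 ± 171 RPM. Of 22 unfolded protein response genes 11 rose and 1 fell, with 13 rises adjusted over the list alone and 7 without DT replicate 3 (camera, adjusted p = 2.45e-05; adjusted p = 0.126 with an estimated correlation), with Calr, a chaperone of the endoplasmic reticulum, from 219 ± 45.8 to 496 ± 59.8 RPM. Oxidative phosphorylation genes fell in 15 of 35, 17 adjusted over the list alone, with a median log2 change of -0.45 (camera, adjusted p = 0.000206; adjusted p = 0.512 with an estimated correlation). That count was 27 without PBS replicate 1 or with sample weights, 8, 7 and 3 without DT replicate 1, 2 and 3, 3 under median-ratio scaling, and 9 without a filter or without the trend. S phase genes fell in 13 of 27, 15 adjusted over the list alone, with a median of -0.56 (camera, adjusted p = 0.000626; adjusted p = 0.284 with an estimated correlation), and in 8 without PBS replicate 4, 6, 8 and 4 without DT replicate 1, 2 and 3, 4 under median-ratio scaling, 5 without a filter and 8 without the trend. Ccne1, a cyclin of the entry into S phase, fell from 28.2 ± 10.3 to 6.51 ± 1.65 RPM. Of 48 ribosomal protein genes 46 fell, 47 adjusted over the list alone and 29 without DT replicate 3, with a median of -0.89 (camera, adjusted p = 3.86e-13; adjusted p = 0.514 with an estimated correlation). Their many pseudogenes make these values uncertain.

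In lists named for endothelial and niche functions, the genes that rose included several known from leukocytes. Of 8 sinusoidal genes Vcam1, Fcgr2b and Mrc1 rose (camera, adjusted p = 0.0455; adjusted p = 0.262 with an estimated correlation), all known from macrophages too. The list missed the threshold without PBS replicate 1 (0.0557) or DT replicate 3 (0.0597) and under quantile (0.0509) or median-ratio scaling (0.0772) and with sample weights (0.0724). Vcam1, an adhesion molecule of vessels and macrophages, rose from 10.6 ± 2.74 to 192 ± 126 RPM, and Mrc1 lost its call without PBS replicate 2, 3 or 4 or DT replicate 2 or 3. Of 11 niche factor genes 4 rose (camera, adjusted p = 0.00412; adjusted p = 0.262 with an estimated correlation), including Jag1, a Notch ligand, and Il15, a lymphocyte growth factor. Scavenger genes rose in 6 of 13 and fell in 2 (camera, adjusted p = 0.00161; adjusted p = 0.178 with an estimated correlation), coagulation genes in 3 of 8 (camera, adjusted p = 0.00445; adjusted p = 0.136 with an estimated correlation) and lipid handling genes in 6 of 17, with 1 fall (camera, adjusted p = 0.0165; adjusted p = 0.262 with an estimated correlation). Plaur, the urokinase receptor, rose from 15.5 ± 2.60 to 356 ± 56.6 RPM and Lpl, lipoprotein lipase, 9.36-fold. Pan-endothelial genes had 2 rises and 1 fall among 11, with 4 rises under sample weights (camera, adjusted p = 0.449). Only 3 arterial genes could be tested, too few for a set test, and Ly6a, Ly6c1 and Bmx each rose.

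**Figure D2:**
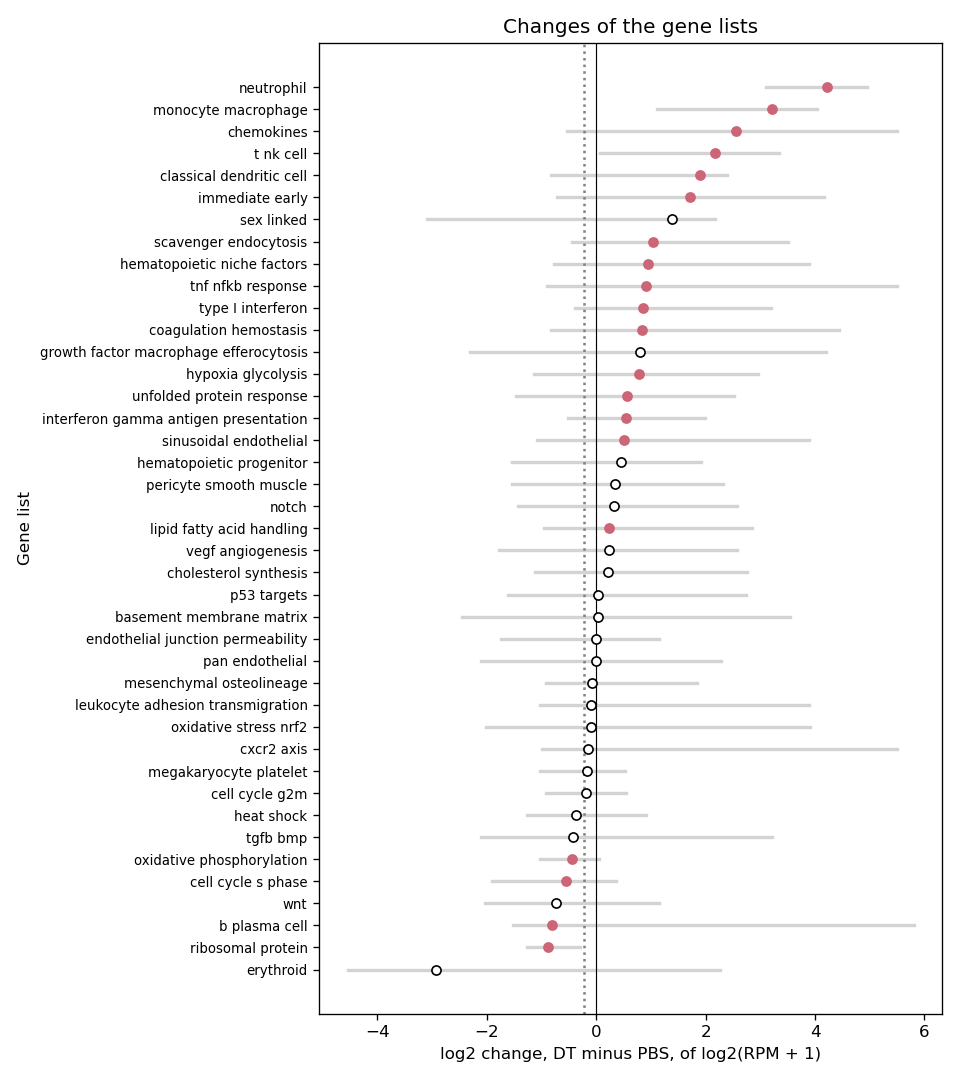
Log2 change, DT minus PBS, of log2(RPM + 1) for each tested gene list; points are medians over members, grey lines run from the lowest to the highest member, filled points pass camera with the preset correlation, and the dotted line is the median of all genes at -0.23. Medians run from -2.93 for erythroid to 4.22 for neutrophil genes.

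The remaining pathway lists missed the threshold in camera. Their adjusted p was 0.0647 for cholesterol synthesis, 0.0882 for Wnt, 0.145 for heat shock and for efferocytosis factors, 0.2504 for VEGF and for Notch, 0.357 for p53 targets and for oxidative stress, 0.449 for leukocyte adhesion, 0.684 for junctions, for G2/M and for basement membrane, and 0.964 for TGF-beta. Cholesterol synthesis passed without PBS replicate 2 (0.0484), PBS replicate 4 (0.0255) or DT replicate 3 (0.0432) and under quantile (0.0423) or median-ratio scaling (0.0438), without a filter (0.0431) and with a minimum mean of 5 RPM (0.0475). Wnt passed under median-ratio scaling (0.0392) and with a minimum mean of 5 RPM (0.0139), heat shock without PBS replicate 1 (0.0174), and efferocytosis factors without a filter (0.0442). With fry, which compares no other genes, the Cxcr2 axis (0.00609), Wnt, efferocytosis and leukocyte adhesion (each 0.00611), Notch (0.0224) and p53 (0.0356) lists passed. Hmox1, which degrades heme, rose from 13.9 ± 3.11 to 200 ± 130 RPM, and Lgr5, a Wnt receptor gene, fell from 50.3 ± 7.73 to 11.8 ± 3.80 RPM. Mesenchymal and pericyte lists were at adjusted p of 0.582 and 0.545, and the sex-linked list at 0.347. In exact permutation tests of list means, the dendritic, macrophage, neutrophil, T and natural killer, progenitor and ribosomal protein lists reached the smallest p of 0.0286, or 0.0571 adjusted, and missed the threshold. The same test, which was not planned for the 30 pathway lists, put 20 of them at 0.0286, or 0.0429 adjusted, and so past the threshold. They included the Cxcr2 axis, VEGF, p53, Wnt, leukocyte adhesion and efferocytosis lists, which missed it in camera, and not oxidative phosphorylation (0.0816 adjusted), which passed in camera. This test takes in genes under the filter and does not compare a list with other genes. Lists of both families share the smallest p of 0.0286, and its adjusted value depends on the share of a family that reaches it. Passing or missing here is thus no measure of strength. The mean log2 level differed by 4.03 for the neutrophil list, which missed, and by 0.25 for VEGF, which passed. The erythroid list was at 0.114 and the B-lineage list at 0.200 before adjustment.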

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

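All tests of explanations in this part were chosen after the results were seen, on the same data. Among 212 sets of 4 PBS values tested for a library far from the others, 7 stood apart, where chance gives about 1 in 20, or 10.6. PBS replicate 1 had a mean log2 level of monocyte and macrophage genes of 2.62, against 2.11 to 2.19 in the other PBS libraries. Its log2 level of Car1 was 7.85 against 11.19 to 11.83, and that of Atp1b2 was 4.16 against 7.18 to 7.71. Ccl3 was at 1.84 in PBS replicate 4, against 0.41 to 0.53. In PBS replicate 2, Perp was at 0.14 and Cebpa at 0.072, against 1.25 to 1.41 for Cebpa and the lowest listed value for Perp in the others. Cd8a was at 0.074 in PBS replicate 3 and at the lowest listed value in the others. Y-linked genes summed to 224 RPM in DT replicate 1 and to 0.242 to 0.633 RPM elsewhere, and Xist, expressed in female cells, was at 1.27 RPM there at 180 RPM in both other DT libraries and at 312 to 413 RPM in PBS. Without DT replicate 1 Xist passed the threshold, with a log2 change of -0.99 (adjusted p = 0.00437). Without that library 1526 genes were higher and 1500 lower.

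The number of genes past the threshold between DT and PBS was 4516. Only 1 of the 35 splits of the 7 samples, the real one, gave as many. This share of 0.0286 is the smallest that 35 splits allow, so it argues against chance assignment of the samples but cannot exclude it. The highest other split gave 1942 genes and set PBS replicates 2, 3 and 4 against the rest, which points to PBS replicate 1 standing apart.

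Low values of many endothelial genes and high blood cell RNA were seen in every library. Loss of long transcripts is argued against, since B-lineage, neutrophil and progenitor genes of the same lengths as endothelial markers had a median 28.6 times higher, with 6 and 16 genes and 1 endothelial gene above the blood cell median. Blood cells in the sort remain a candidate source, as the median B-lineage gene was at least 164 times the median pan-endothelial gene in each library. The gate on CD45, Ter119, Gr1 and CD11b is meant to remove most such cells. Ptprc, which encodes CD45, was nonetheless at 171 ± 53.4 RPM in PBS and 473 ± 64.0 RPM in DT, so the gate did not keep blood cell RNA out. No biological explanation was tested, since both groups show the pattern.

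Neutrophil genes and Cxcr2 were higher in DT. Library scaling is argued against by a median log2 change of the neutrophil list of at least 3.95 under 3 other scalings, and the library with Y-linked RNA by 4.17 without it. More neutrophil-lineage RNA in the DT libraries may account for the rise of Cxcr2, since 2 of the 17 listed genes, which leave out Cxcr2, rose more. The gate on Gr1 and CD11b is meant to remove neutrophils that carry these antigens. RNA of Itgam, which encodes CD11b, was nonetheless at 25.8 ± 7.78 RPM in PBS and 304 ± 13.4 RPM in DT. Ly6g, part of the Gr1 epitope, was at 5.72 ± 0.957 and 70.7 ± 2.90 RPM. The log2 change of Cxcr2, 4.84, lay within the range of the 17 genes, 3.11 to 4.96. The ratio of Cxcr2 to the sum of 12 endothelial genes, chosen after their values were seen, was 0.733 to 3.74 in PBS and 14.0 to 29.0 in DT. This ratio cannot tell induction of Cxcr2 in endothelial cells apart from more neutrophil-lineage RNA, because more Cxcr2 RNA from either source would raise it. An effect of dendritic cell ablation on marrow neutrophils stays open and untested.

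Early erythroid genes were lower in DT. Loss of all erythroid RNA is argued against by 4 globin and Alas2 genes that rose, of which only Alas2 passed without a filter, although free red cell RNA was not tested. Library scaling is argued against by a median log2 change of the fallen genes of -3.45 or lower under 3 other scalings. A varying number of erythroid progenitors in the sort is a candidate explanation that these data do not decide. All 10 fallen genes were lowest among PBS libraries in PBS replicate 1. Genes of a lineage that move together would show this whatever lowered them in DT. The gate on Ter119 would remove erythroid cells that carry that antigen. An effect of DT on erythroid cells stays open.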

How the results depend on the processing

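Voom on estimated reads and leaving out both replicates numbered 1 were chosen after the data were seen. The number of genes higher in DT stayed within 1.5 times of 1894 in all alternatives run, from 1383 without DT replicate 3 to 2394 with median-ratio scaling. The number lower, 2622, became 1709 without a filter on low values, 1255 with median-ratio scaling and 1050 with a log2 change of at least 1. It ranged from 1208 to 3628 when single libraries were left out. Fewer samples and a stricter limit account for part of this, and the cause of the others was not tested. With an estimated correlation 0 lists of either family were higher and 0 lower, whereas fry, which compares no other genes, gave 17 pathway lists higher and 3 lower. The cell type and quality lists lower in DT numbered 1 without the trend, and 1 to 2 when single libraries were left out. Deviations of same-numbered samples correlated at 0.042, 0.049 and 0.010, and those of other pairs at -0.048 to 0.019. PBS replicates 1 and 2 correlated best with the DT replicate of the same number, and PBS replicate 3 with DT replicate 2 (0.019). Correlations this weak neither show nor exclude pairing, and the labels state none. A replicate block gave 1647 genes higher and 1574 lower, with 3118 of the 4516 genes shared. Under it Zbtb46 (adjusted p = 0.0120), Cxcl12 (0.0127), Ppbp (0.0263) and cholesterol synthesis (0.0332) passed, which they had not in the main fit, and Mrc1 (0.120), Spp1 (0.0506), Cdc20 (0.0953), Hspe1 (0.0607), Hsph1 (0.0643), Atp5j (0.0558), Flt3 (0.0506), Laptm5 (0.0653) and Cnn1 (0.0606) no longer did.

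Directions turned only in lists and genes that passed in neither setting. The cause was not tested. The test's direction and the median can differ in sign. Junction genes turned at median log2 changes of -0.027 without a filter, -0.21 with a mean of at least 5, 0.24 with median-ratio scaling, -0.52 without both replicates numbered 1 and -0.0029 with fry, with medians of -0.30 to 0.25 when single libraries were left out. G2/M genes turned at -0.089 with sample weights and 0.025 without both replicates numbered 1 (-0.31 to 0.068). TGF-beta genes turned at -0.46 and -0.44 with pseudocounts of 0.1 and 0.5, -0.060 without a filter, -0.21 with median-ratio scaling and -0.48 with the block (-0.48 to -0.33). Megakaryocyte genes turned at -0.19 without a filter, 0.051 with median-ratio scaling, -0.079 with the block, -0.23 without both replicates numbered 1 and -0.17 with fry (-0.42 to 0.37). Pecam1 turned at 0.079 with quantile normalization, 0.24 with median-ratio scaling, 0.054 with sample weights and 0.21 without both replicates numbered 1 (-0.13 to 0.13). Median-ratio scaling turned Pf4 to 0.047 (-0.69 to 0.13) and Ighm to 0.038, which was 0.079 without both replicates numbered 1. Cd2 ranged from -0.18 to 0.22.

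Of the other settings of lists, 807 kept direction and side, 33 lost and 27 gained a call. For named genes 3253 kept both, 88 lost and 16 gained a call. The neutrophil genes were higher in all 17 members under every scaling and without any single library. Depth limits values under about 0.0904 RPM, such as the PBS means of Tie1 (0.0512) and Emcn (0.0792).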

Other observations

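Neutrophil genes of different granules moved by different amounts; the sets were taken from the fixed list after the values were seen. The mean of 6 genes of secondary and tertiary granules, made late in maturation, rose by 4.64 on the log2 scale, and that of 4 genes of primary granules, made early, by 3.16. The difference between these sets was higher in DT by 1.48 (exact permutation p = 0.0286, the smallest possible, n = 4 and 3). Globin genes and Alas2 against early erythroid genes gave a difference higher in DT by 5.30. Plasma cell genes, not all on the fixed lists, against B cell precursor genes gave 7.73. Both had the same exact permutation p and were also chosen after the values were seen. These differences describe the sets and are no independent tests.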
